A study of Mus musculus with 8 samples.

How the data were processed

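Dendritic cells (DCs) were sorted from E0771 tumours, grown from a mouse mammary carcinoma cell line, in wild-type mice given PBS or DRQ, which the labels describe as an inhibitor of CD74. Treatment began on day 10 and tumours were taken 3 weeks after injection, per the labels. The labels give 4 samples per group and do not state whether these are separate mice or pools, so p-values measure the spread between these samples, which may be technical. RNA was measured by a bulk form of MARS-seq, a 3′-end RNA-seq method with unique molecular identifiers (UMIs), per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt, STAR 2.7.3a, HTSeq, DESeq and DESeq2 1.26.0 and the build GRCm39, without saying which step each served.

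The deposited raw table holds whole-number counts per Ensembl gene, with 1 column per sample. It lists 10825 genes, each with at least 6 counts in at least 1 library. Whether the authors collapsed UMIs, and whether counting used strand, is not given in the sources used here, so intervals and floors cover counting error only, and antisense and overlapping genes cannot be told apart. The deposited normalized table holds a signal, counts divided by a size factor per library: all 86600 values equalled the raw count over DESeq2's median-ratio factor within 0.011. It was used for an alternative test only. Gene symbols came from a name table of an annotation of another mouse build, in which 10788 of the 10825 IDs matched; the 37 others held 0.186% of the counts. No coordinates are printed, because a GRCm39 annotation was not used here. Genes with near-identical copies, such as Hspa1a and Hspa1b, Trbc1 and Trbc2, or the haemoglobin genes, are uncertain where counting could split their reads.

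The design, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust quasi-likelihood F test, 2-sided, Benjamini-Hochberg adjustment, threshold 0.05, no fold minimum). The filter kept 6156 genes with 94.9% of the counts. Fold changes are DRQ over PBS on the log2 scale with standard errors (SE), and CPM values are scaled by the TMM factors unless stated otherwise. The common biological coefficient of variation was 0.235. Gene lists, 21 of functions and 15 of cell types, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), where at least 5 members were tested, with Benjamini-Hochberg adjustment within each kind of list. List scores are mean log2 CPM over the tested members in each library, compared by exact 2-sided permutation of the library labels.

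Named genes were those with adjusted p under 0.05, a mean of at least 10 CPM and groups fully apart (up to 12 per direction); Cd74, Mif, Cd44, Cxcr4, Ccr7, H2-Aa and H2-Ab1 whatever their p; up to 4 members of each list with the smallest p in the direction of its median; and, where fewer than 6 genes passed in a direction, the 6 with the smallest unadjusted p. Some genes that this rule takes are not reported here. Alternatives covered other scaling factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, other filters, a replicate block and the deposited normalized table. They also covered a fold minimum, each library left out in turn, an estimated correlation and fry. The other filters were no filter and 5 CPM in at least 4 libraries, and both let in more low-count genes than the main filter. Removing PBS libraries 2 and 3 together, permuting list scores, adding the NK cell list score as a covariate and, for named genes other than Cd74, testing the normalized table were chosen after seeing the data.

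Counts were simulated from the means, library sizes and dispersions of this comparison, over 6156 genes and 3 draws. EdgeR recovered 44.0% of 300 genes changed 2-fold and 91.7% of 300 genes changed 4-fold, and called 27 unchanged genes in all. So many planted changes loosen the adjusted threshold, so recovery may be lower where few genes change. No pair of the 8 libraries agreed within counting noise (chi-square per degree of freedom 2.60 to 4.21), so none was taken for a repeat deposit of another; this does not show that they came from separate mice or RNA pools. Figures were drawn with matplotlib 3.10.9.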

Results

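The data were 3′-end transcript counts of cells labelled as tumour DCs from 4 PBS-treated and 4 DRQ-treated samples of mice bearing E0771 tumours. Total counts per library were 543892, 361792, 366205 and 422609 in PBS replicates 1 to 4 and 497482, 523937, 438648 and 539381 in DRQ replicates 1 to 4. The PBS libraries averaged 423624 ± 84824 counts and the DRQ libraries 499862 ± 44325 (SD, n = 4). At these depths a count of 0 allows a level of up to 5.52 CPM in the deepest library and 8.29 CPM in the shallowest.

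Transcripts of antigen-presenting cells and of cytotoxic lymphocytes were both abundant in all 8 libraries. Gzma, a granule protease of killer cells, ranked 10 among the listed genes by mean CPM, Ccl5 ranked 17, Gzmb 29, Nkg7 102, the pore-forming protein Prf1 106 and the T cell receptor gene Trbc1 126. Cst3, abundant in DCs, ranked 34, Cd74 40 and Irf8, a transcription factor of type 1 conventional DCs, 81. The 12 members of the natural killer (NK) cell and cytotoxic list summed to 14691 ± 1570 CPM in PBS and 13871 ± 1995 CPM in DRQ (unscaled CPM, SD, n = 4), with no detectable difference (exact 2-sided permutation p = 0.571). All 12 NK list members and all 17 T cell list members were counted in all 8 libraries.

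**Figure D1:**
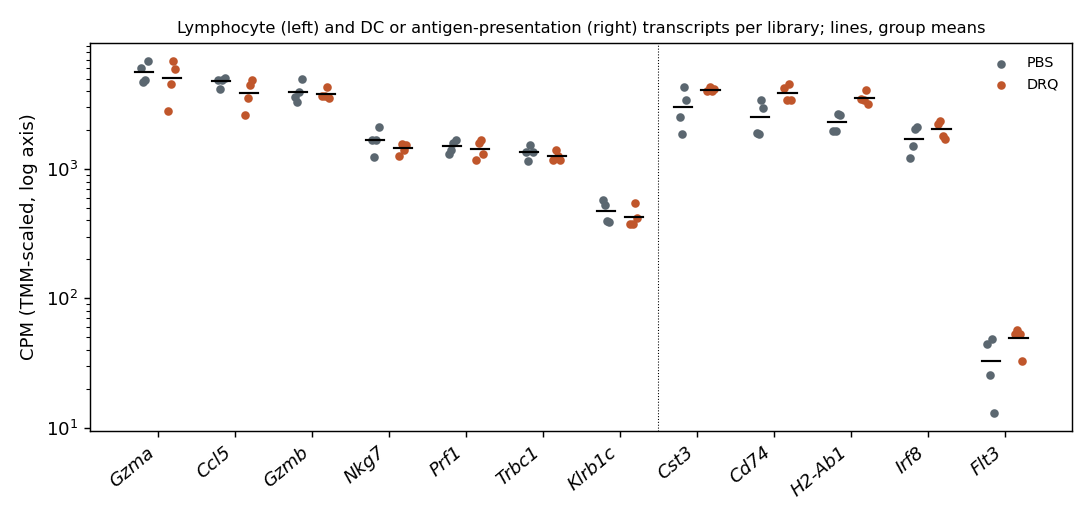
CPM on a log axis for 12 transcripts in each of the 4 PBS (grey) and 4 DRQ (orange) libraries, with lines at group means; lymphocyte transcripts stand left of the dotted line, and DC or antigen-presentation transcripts right. Gzma averaged 5602 CPM in PBS and 5043 CPM in DRQ, and Cd74 2524 CPM in PBS and 3905 CPM in DRQ.

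The comparison of DRQ with PBS asked how an inhibitor of CD74 changed the transcripts of DCs in the tumour. Il1b, which encodes the inflammatory cytokine interleukin-1β, rose from 121 ± 44.8 CPM in PBS to 300 ± 47.8 CPM in DRQ (SD, n = 4). Il1r2, which encodes a decoy receptor for interleukin-1, rose from 111 ± 13.4 to 260 ± 52.9 CPM (SD, n = 4). All 4 DRQ libraries lay above all 4 PBS libraries for both genes. Which cells these transcripts came from was not tested, and the libraries also held abundant lymphocyte transcripts. Their log2 fold changes were 1.30 ± 0.22 for Il1b (ENSMUSG00000027398) and 1.21 ± 0.20 for Il1r2 (ENSMUSG00000026073), each with adjusted p = 0.00758 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

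**Figure D2:**
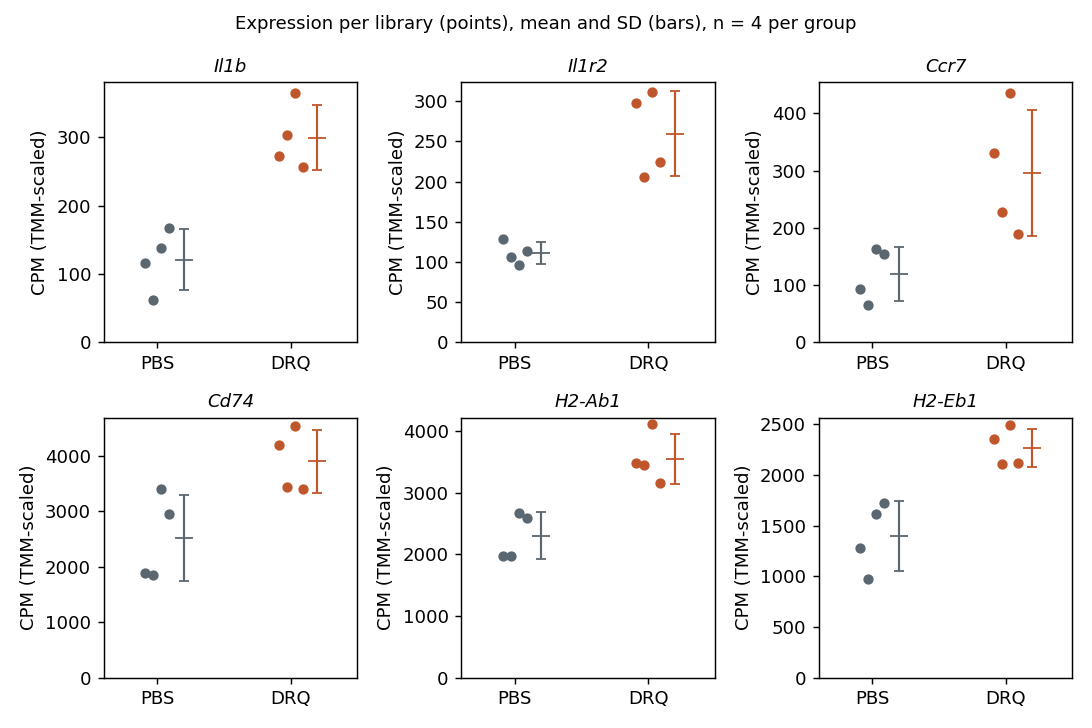
CPM of 6 genes in each library (points; linear axes from 0), with the group mean and SD beside the 4 points of each group. For all 6 genes the lowest DRQ library lay above the highest PBS library; Il1b ranged from 61.8 to 168 CPM in PBS and from 257 to 365 CPM in DRQ.

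These were the 2 genes called among the 6156 tested with edgeR, both higher, and 0 were called lower. At an unadjusted p under 0.05 edgeR gave 245 genes higher and 202 lower, where 308 would pass by chance. DESeq2, which gave an adjusted p to 2011 of these genes, called 17, 16 higher and 1 lower, and limma-voom called 2 of the 6156. Groups were fully apart for 132 genes higher and 134 lower, 4.32% of those tested, against 2.86% by chance. Without DRQ replicate 3 both calls ended (adjusted p = 0.0709 for each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment); both estimates stayed above 0, at 1.12 for Il1r2. The count was 6 without PBS replicate 3, 15 without PBS replicate 4, 7 without DRQ replicate 4, and 0 without PBS libraries 2 and 3 together, a removal chosen after seeing the data.

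Of the genes that did not pass, Junb, H2-Ab1, H2-Eb1 and Vps37b had the smallest unadjusted p. Junb, an AP-1 transcription factor, had a log2 fold change of 0.67 ± 0.14 and Vps37b, of the endosomal sorting machinery, 0.73 ± 0.15; each was called in 5 of its 20 alternative fits. H2-Ab1 and H2-Eb1 encode MHC class II chains and are described with that group. In the other direction, values were -1.19 ± 0.28 for Prpsap1, -1.40 ± 0.37 for Mri1, -1.43 ± 0.39 for Smyd2, -1.31 ± 0.36 for Akt1s1 and -1.21 ± 0.35 for Lrrc45. The adjusted p of these lower values ran from 0.127 for Prpsap1 to 0.287 for Lrrc45 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so none of the 5 passed there. Prpsap1 was called lower by DESeq2 (Benjamini-Hochberg adjusted p = 0.0345) and by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without PBS replicate 4 (log2 fold change -1.42, adjusted p = 0.0186).

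Cd74 (ENSMUSG00000024610), which encodes the MHC class II invariant chain and is the stated target of DRQ, averaged 2524 ± 779 CPM in PBS and 3905 ± 565 CPM in DRQ (SD, n = 4). Its log2 fold change was 0.63 ± 0.18 and did not pass over all genes (adjusted p = 0.317 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). All 4 DRQ libraries lay above all 4 PBS libraries, the nearest pair at 3409 CPM in PBS replicate 3 and 3413 CPM in DRQ replicate 4. DESeq2 called it among the 2011 genes it adjusted (log2 fold change 0.64, Benjamini-Hochberg adjusted p = 0.0440), and so did edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without PBS replicate 3 (log2 fold change 0.81, adjusted p = 0.0187). The transcript level says nothing of whether the protein was inhibited. Other members of the CD74 and MIF list did not pass, with Cxcr4 at 0.74 ± 0.29, Cd44 at 0.39 ± 0.25 and Mif at -0.14 ± 0.15; Cd44 fell to 0.13 without DRQ replicate 2 and Mif stood at -0.06 without PBS replicate 4. Over the 9 tested members 0 passed over all genes with edgeR and 1, Cd74, was higher when adjusted over the list alone, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.232).

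MHC class II presentation transcripts were higher in DRQ as a list. All 11 tested members had estimates above 0, with a median of 0.37. H2-Ab1 averaged 2304 ± 384 CPM in PBS and 3552 ± 401 CPM in DRQ, H2-Eb1 1397 ± 343 and 2267 ± 185 CPM, and H2-Aa 1690 ± 447 and 2473 ± 246 CPM (SD, n = 4). Their log2 fold changes were 0.62 ± 0.13, 0.70 ± 0.14 and 0.55 ± 0.15, with adjusted p of 0.0515, 0.0515 and 0.218 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so 0 members passed over all genes and 3 were higher when adjusted over the list alone. DESeq2 called H2-Ab1 and H2-Eb1 among the 2011 genes it adjusted (Benjamini-Hochberg adjusted p = 0.00141 and 0.00285), and H2-Ab1 was called in 9 of its 20 alternative fits, of which 3 were chosen after seeing the data. Ciita, the master regulator of these genes, stood at 0.47 ± 0.23. The list was called by camera with Benjamini-Hochberg adjustment (adjusted p = 0.000263), and not with an estimated correlation (adjusted p = 0.175 with an estimated correlation). The conventional DC list, given further on, was higher in the same libraries by camera with the preset correlation, not with an estimated one.

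Transcripts of the mature regulatory DC program, which marks DCs that mature and migrate to lymph nodes, were higher in DRQ, and all 21 tested members had estimates above 0 with a median of 0.69. Ccr7, the lymph node homing receptor, averaged 119 ± 47.5 CPM in PBS and 296 ± 111 CPM in DRQ (SD, n = 4; log2 fold change 1.32 ± 0.29). Cacnb3 stood at 1.45 ± 0.35, the costimulatory receptor gene Tnfrsf4 at 0.69 ± 0.17 and the actin-bundling gene Fscn1 at 0.70 ± 0.24. Over all genes 0 members passed with edgeR, and 7 were higher when adjusted over the list alone; DESeq2 called Ccr7 and Tnfrsf4 among the 2011 genes it adjusted (Benjamini-Hochberg adjusted p = 0.00285 and 0.0362). Over all genes edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called Ccr7 without DRQ replicate 4 (1.48, adjusted p = 0.0306) and with a replicate block (1.32, adjusted p = 0.0121), and Cacnb3 without PBS replicate 3 (1.97, adjusted p = 0.0187). The list had the smallest p of the 21 function lists (camera with Benjamini-Hochberg adjustment, adjusted p = 1.22e-10), but adjusted p = 0.163 with an estimated correlation. Of its 25 symbols 8 also stand in other lists. The conventional DC, type 2 conventional DC (cDC2) and T cell lists, given further on, were higher in the same libraries by camera with the preset correlation, not with an estimated one. Activated T cells also transcribe Tnfrsf4. Which cells the other members came from, Ccr7 and the abundant Tnfrsf9 (mean 688 CPM) among them, was not tested.

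Inflammatory and signalling lists were also called higher in DRQ. In the NF-kB and inflammatory cytokine list 17 of 18 tested members had estimates above 0, 1 (Il1b) rose over all genes with edgeR, and 4 were higher when adjusted over the list alone; among the 2011 genes it adjusted DESeq2 called Il1b and also Tnfaip3 (Benjamini-Hochberg adjusted p = 0.0325 for Tnfaip3). Tnfaip3, an inhibitor of NF-kB signalling, stood at 0.73 ± 0.17, the interleukin-1 receptor antagonist Il1rn at 1.32 ± 0.42 and the NF-kB inhibitor Nfkbia at 0.38 ± 0.13. The list had adjusted p = 6.19e-06 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.209 with an estimated correlation. Of the 10 chemokines tested 8 had estimates above 0, among them Cxcl16 at 1.40 ± 0.35 and Ccl22 at 1.27 ± 0.41, with 0 passing over all genes with edgeR and 2 higher when adjusted over the list alone. The chemokine list had adjusted p = 0.00341 by camera with Benjamini-Hochberg adjustment, adjusted p = 0.457 with an estimated correlation, and 0.135 without PBS replicate 2. The conventional DC, cDC2 and T cell lists were again higher in the same libraries by camera with the preset correlation, not with an estimated one.

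Immunosuppressive mediators had estimates above 0 in 10 of 13 tested members, with 0 passing over all genes with edgeR and 1, Tgfb1 at 0.73 ± 0.19, higher when adjusted over the list alone. Il4i1, an amino acid oxidase that also stands in the mature regulatory DC list, was at 0.71 ± 0.27. This list had adjusted p = 0.00341 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.175 with an estimated correlation. Of the 15 symbols in the list of costimulatory molecules and T cell priming cytokines 5 were tested. These were Cd83, Icosl, Tnfsf9, Cd40 and Icam1, and no interleukin gene was among them. All 5 had estimates above 0, with the maturation marker Cd83 at 0.69 ± 0.28 (0.42 without DRQ replicate 3). With edgeR none of the 5 passed over all genes or when adjusted over the list alone (0 and 0). The list had adjusted p = 0.0164 by camera with Benjamini-Hochberg adjustment, adjusted p = 0.175 with an estimated correlation, and 0.0976 without PBS replicate 2. The same 3 cell type lists were higher in these libraries, again with the preset correlation and not with an estimated one.

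Interferon response transcripts were higher as lists. Of 28 tested type I interferon genes 24 had estimates above 0, among them Ifi27l2a at 0.49 ± 0.16 and Trim30a at 1.13 ± 0.37, with 0 passing over all genes with edgeR and 0 when adjusted over the list alone. This list had adjusted p = 0.000227 by camera with Benjamini-Hochberg adjustment, adjusted p = 0.457 with an estimated correlation, and 0.0743 without PBS replicate 2. Of 16 interferon gamma genes 11 had estimates above 0. The GTPase gene Gbp5 stood at 1.03 ± 0.38, and with edgeR 0 members passed over all genes against 1 when adjusted over the list alone. The interferon gamma list had adjusted p = 0.0188 by camera with Benjamini-Hochberg adjustment and adjusted p = 0.457 with an estimated correlation. It also lost its call without PBS replicate 2 (0.189), PBS replicate 3 (0.0528) or DRQ replicate 1 (0.184). Here too the conventional DC, cDC2 and T cell lists were higher in the same libraries with the preset correlation, not with an estimated one.

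**Figure D3:**
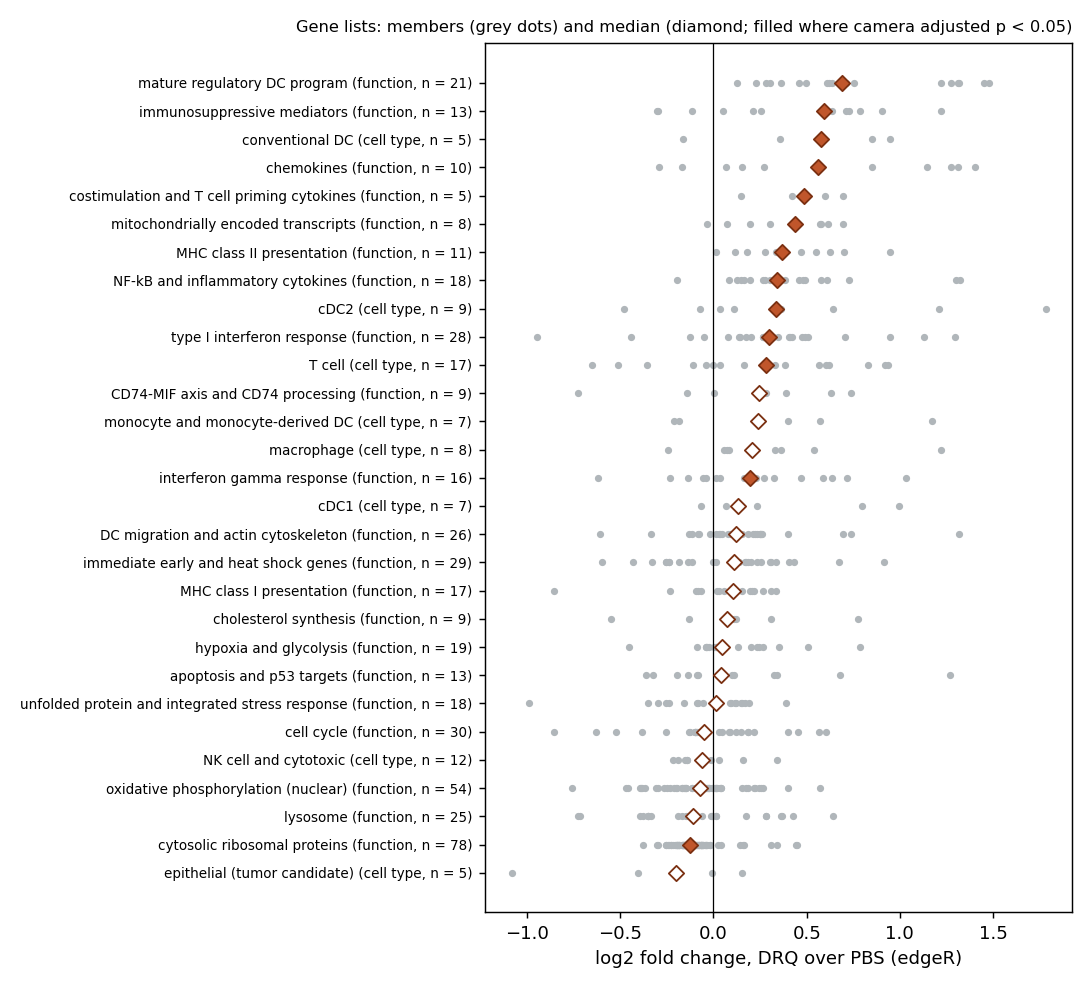
Log2 fold changes (DRQ over PBS, edgeR) of each tested member (grey dots) of the 29 lists with at least 5 tested members, and their medians (diamonds, filled where camera's adjusted p with the preset correlation was under 0.05). Among the filled diamonds the mature regulatory DC program had the highest median, 0.69, and the cytosolic ribosomal proteins the only one below 0, at -0.13.

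Mitochondrially encoded transcripts were higher as a list, with 7 of 8 tested members above 0 and mt-Cytb at 0.57 ± 0.25, and with edgeR 0 members passed over all genes or when adjusted over the list alone. The list had adjusted p = 0.00994 by camera with Benjamini-Hochberg adjustment, adjusted p = 0.534 with an estimated correlation, and lost its call without PBS replicate 1 (0.162), PBS replicate 2 (0.205) or DRQ replicate 3 (0.0927). Cytosolic ribosomal proteins were lower as a list, with 69 of 78 tested members below 0, among them Rpl3 at -0.30 ± 0.11 and Rpl10a at -0.38 ± 0.13, and 0 passing either way with edgeR. In DRQ replicate 1 the list averaged 10.60 log2 CPM, apart from the other 3 DRQ libraries (10.89 to 10.90), which lay inside the PBS range of 10.72 to 11.07. That list had adjusted p = 0.00341 by camera with Benjamini-Hochberg adjustment, adjusted p = 0.708 with an estimated correlation, and lost its call without PBS replicate 3 (0.192) or DRQ replicate 1 (0.355).

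Of the 21 function lists 10 were thus called, 9 higher and 1 lower, and 0 with an estimated correlation. Some of them share genes and so are not separate findings. Symbols also in other lists numbered 8 in the mature regulatory DC list, 6 each in immunosuppressive mediators and interferon gamma and 4 in chemokines. There were 2 each in MHC class II and NF-kB, 1 in costimulation, and 0 in type I interferon, mitochondrial transcripts and ribosomal proteins. At an unadjusted p under 0.05 edgeR gave 9 members higher in the mature regulatory DC list, 3 in MHC class II, 6 in NF-kB, 3 in chemokines, 4 in immunosuppressive mediators, 1 in costimulation, 3 in interferon gamma and 1 in mitochondrial transcripts, with 0 lower in each; it gave 6 higher and 1 lower in type I interferon and 1 higher and 8 lower in ribosomal proteins. By fry, which tests whether a list's genes move on balance in 1 direction, 4 were called: the mature regulatory DC, MHC class II, costimulation and immunosuppressive lists (each Benjamini-Hochberg adjusted p = 0.0351). Exact 2-sided permutation of the libraries, chosen after seeing the data, gave 5 lists the smallest p it can give, 0.0286, and Benjamini-Hochberg adjustment of those values called 0 lists. With 21 lists, an adjusted p under 0.05 would need far more than 5 lists at that smallest p. The 0 calls by permutation thus argue little against the lists.

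Markers of conventional DCs, cDC2 and T cells were higher in DRQ as lists by camera with the preset correlation, and 0 cell type lists were called with an estimated one. Conventional DC markers had 4 of 5 tested members above 0, including Flt3, the receptor for a DC growth factor, at 0.57 ± 0.39 (0.31 without PBS replicate 4), while Itgax stood at -0.16 ± 0.19 (-0.08 without PBS replicate 1 and -0.28 without DRQ replicate 4). The cDC2 markers had 7 of 9 above 0. Il1r2 rose over all genes, and when adjusted over the list alone Il1r2 and the lectin gene Mgl2, at 1.78 ± 0.41, were higher and Cd7, at -0.48 ± 0.15, was lower. T cell markers had 11 of 17 above 0, including Cd5 at 0.94 ± 0.29, Cd3d at 0.83 ± 0.26, Cd4 at 0.92 ± 0.33 and Trac at 0.56 ± 0.20; 0 passed over all genes with edgeR (6 higher and 1 lower at an unadjusted p under 0.05), and 5 were higher and 1, Skap1 at -0.51 ± 0.16, lower when adjusted over the list alone.

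Each of these 3 cell type lists had adjusted p = 0.0259 by camera with Benjamini-Hochberg adjustment. The values were adjusted p = 0.223, 0.279 and 0.308 with an estimated correlation for the conventional DC, cDC2 and T cell lists. Without DRQ replicate 1 all 3 lost their calls (0.0740, 0.0740 and 0.0787); the conventional DC list did so also without PBS replicate 2 (0.0549) or PBS replicate 4 (0.0847), and the T cell list without the same libraries (0.247 and 0.0951). The NK cell and cytotoxic list was not called (median -0.06, adjusted p = 0.532 by camera with Benjamini-Hochberg adjustment), with 0 of 12 members passing with edgeR and 0 at an unadjusted p under 0.05; log2 fold changes were -0.15 ± 0.27 for Gzma, -0.22 ± 0.14 for Nkg7 and -0.14 ± 0.16 for Klrb1c. The other 4 tested cell type lists were not called, with adjusted p by camera with Benjamini-Hochberg adjustment of 0.0550 for type 1 conventional DCs, 0.0869 for monocytes and monocyte-derived DCs, 0.613 for macrophages and 0.268 for epithelial cells. Of 16 alternatives each, the type 1 conventional DC list was called higher in 2 (library size alone, 0.0464, and without DRQ replicate 4, 0.0464). The monocyte list was called higher in 4 (no filter, 0.0246, the looser 5 CPM filter, 0.0313, without PBS replicate 1, 0.0400, and without PBS replicate 3, 0.0299). The epithelial list was called lower in 1 (without PBS replicate 3, 0.0391). Another 7 lists had fewer than 5 tested members and were not tested.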

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

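Among 190 groups of 4 libraries checked for a library standing far from the others, 6 did so, where chance gives about 1 in 20, or 9.5. The gap of the outlying library to its nearest neighbour, as a share of the whole range of the group, is given for each. In DRQ replicate 3, Trim30a stood at 6.66 log2 CPM against 5.62 to 5.78 in the other DRQ libraries (gap 0.853), and the MHC class I list averaged 9.04 against 9.19 to 9.21 (gap 0.878). In DRQ replicate 4, Flt3 stood at 5.23 log2 CPM against 5.85 to 5.94 (gap 0.867). In DRQ replicate 1 the list of nuclear oxidative phosphorylation genes averaged 7.51 against 7.83 to 7.90 (gap 0.832), and the cytosolic ribosomal protein list 10.60 against 10.89 to 10.90 (gap 0.972). In PBS replicate 3 the epithelial list averaged 3.99 against 5.67 to 5.94 in the other PBS libraries (gap 0.865).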

How the results depend on the processing

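Removing PBS libraries 2 and 3, permuting list scores, the NK covariate and, for genes other than Cd74, the normalized table were chosen after seeing the data. Against the main 2 genes called (2 higher, 0 lower), library size alone gave 7 (7 higher), DESeq2, over 2011 genes, 17 (16 higher, 1 lower), no filter 8 (7 higher, 1 lower), the normalized table only 1 (1 higher), PBS libraries 2 and 3 removed 0 (0 higher) and the NK list score as a covariate 4 (4 higher). Leaving out 1 library gave 0 to 15 calls, 0 to 14 higher and 0 to 1 lower. The log2 fold change of Cd74 passed with DESeq2 (0.64) and ran from 0.50 to 0.81 with 1 library left out. Against 10 function lists, an estimated correlation gave 0, fry 4, permutation 0 and 1 library left out 6 to 11. Permutation with adjustment could hardly call a list, given the smallest p it can give. Against 3 cell type lists, an estimated correlation gave 0, fry 0, permutation 0, no filter 5, the looser 5 CPM filter 5 and 1 library left out 0 to 5. Fewer libraries or other genes entered these fits where libraries were left out or filters changed; otherwise the cause was not tested.

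With a replicate block 6 genes were called (6 higher), the 2 main ones among them, with 10 function and 3 cell type lists. Same-numbered libraries correlated at -0.01 to 0.08 after removing group means, others at -0.08 to 0.06, and 4 of 8 libraries correlated best with their own number. These values do not settle whether equal numbers pair samples. The main test used no block, because nothing in the labels states a pairing. Over all fits of the genes named here, 1232 values kept side and sign, 38 passed where the main value had not, 5 no longer passed (Il1b and Il1r2 without DRQ replicate 3 and without PBS libraries 2 and 3, and Il1b, at 1.37, on the normalized table) and 5 changed sign, none of them called: Gzma (-0.331 to 0.0538 with 1 library left out, above 0 without DRQ replicate 1), Gzmb (-0.149 to 0.0592, above 0 without PBS replicate 4) and Prf1 (-0.136 to 0.0387, above 0 without DRQ replicate 1 and, at 0.0039, without PBS replicate 4, and at 0.0186 with the NK covariate). DESeq2 gave some of these genes no adjusted p, and such values were counted as not passing. The 1232 thus include fits without a verdict. At these depths edgeR missed most simulated 2-fold changes.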

Other observations

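The comparison with DC identity genes, the T cell receptor and CD3 sum, the further lymphocyte genes and the regulatory T cell and CD8 lists were tests chosen after the results were seen, of which the further lymphocyte genes had their bounds set before their own values were seen; thinning and regrouping of the libraries were set before.

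Further cell type and stress transcripts are given as values. Krt8, a keratin of epithelial cells, averaged 155 ± 41.8 CPM in PBS and 73.6 ± 38.3 CPM in DRQ, and Sparc, a fibroblast matrix gene, 111 ± 38.1 and 64.5 ± 28.9 CPM (SD, n = 4); neither passed over all genes, and each was lower when adjusted over the list alone. Ighm, an immunoglobulin gene, averaged 255 ± 40.8 and 374 ± 95.8 CPM. Mmp9, a neutrophil protease, stood at 554 ± 670 CPM in PBS and 116 ± 96.5 CPM in DRQ (SD, n = 4), with 1536 CPM in PBS replicate 2 and 103 to 427 CPM in the other PBS libraries. Hbb-bs, a haemoglobin gene, stood at 171 ± 123 and 633 ± 829 CPM (SD, n = 4), with 1869 CPM in DRQ replicate 4 and 102 to 332 CPM in the other DRQ libraries. The heat shock gene Hspa1b ranked 42 by mean CPM, with 3371 ± 1014 CPM in PBS and 2686 ± 498 CPM in DRQ. Nr4a3, an immediate early gene, stood at 0.91 ± 0.25 and the cell cycle inhibitor Cdkn1a at 0.68 ± 0.19 on the log2 scale, each higher when adjusted over its list alone and not over all genes. Without PBS replicate 4 Cdkn1a passed over all genes (log2 fold change 0.91, adjusted p = 0.0281 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

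The remaining function lists were not called by camera with Benjamini-Hochberg adjustment. Their adjusted p was 0.0532 for DC migration and the actin cytoskeleton, 0.165 for nuclear oxidative phosphorylation (below 0), 0.232 for hypoxia and glycolysis and for immediate early and heat shock genes, 0.317 for MHC class I presentation, 0.563 for apoptosis and p53 targets, 0.566 for the lysosome, 0.578 for cholesterol synthesis and 0.970 for the cell cycle and the unfolded protein response. In the unfolded protein list the median was above 0 (0.02) while the test's direction was below. Of 16 alternatives the DC migration list was called higher in 6 (library size alone, 0.0382, no filter, 0.0406, the looser 5 CPM filter, 0.0365, and without PBS replicate 3, 0.0277, PBS replicate 4, 0.0120, or DRQ replicate 3, 0.0302). Oxidative phosphorylation was called lower in 3 (without PBS replicate 1, 0.0238, PBS replicate 2, 0.0415, or DRQ replicate 2, 0.0428) and turned above 0 without DRQ replicate 1 (0.875), and hypoxia and glycolysis was called higher in 1 (without PBS libraries 2 and 3 together, 0.0275, chosen after seeing the data).

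Mature DC and MHC class II transcripts were higher in DRQ, by 0.73 and 0.41 in mean log2 CPM. Camera called both lists at the preset correlation but not with an estimated one (Benjamini-Hochberg adjusted p = 0.163 and 0.175). Exact permutation with Benjamini-Hochberg adjustment did not call them (adjusted p = 0.12 for each), though it could hardly have called any list. A score of 20 DC identity genes was higher by 0.39 (exact 2-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The mature list's score lay below the identity score by 0.60 in PBS and 0.26 in DRQ, a difference of 0.34 (exact 2-sided permutation p = 0.0286). This does not exclude a larger share of DC RNA as the cause. The identity genes were not shown to come from DCs alone in these libraries, and activated T cells also transcribe Tnfrsf4 of the mature list. The source cells of that list's other members were not tested either. For the MHC class II list the same difference was 0.0245 (exact 2-sided permutation p = 0.771), so a larger share of DC RNA may account for it. Thinning every library to 361792 counts left differences of 0.70 ± 0.02 and 0.41 ± 0.02 (SD over 20 draws), which argues against depth. A response of DCs to DRQ and a change in the mix of DC states or of activated T cells stay open, untested.

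NK and T cell transcripts were among the most abundant in libraries labelled DCs. Of 16 further lymphocyte genes, picked once this pattern was known and so likely to follow it, 14 had more than 3 counts in every library (not Il7r or Cd28), as RNA of NK and T cells in the sorted samples would give; the labels state no gate, and this explanation stays open. Cytotoxic DCs without lymphocyte RNA are argued against by T cell receptor and CD3 genes, which summed to 1689 CPM or more in each library (unscaled CPM). The largest parts were Trbc1 and Trbc2, at least 1119.8 and 351.03 CPM, near-identical copies between which reads may be split. The largest floor, 8.29 CPM, holds for a single gene and not for the sum. Taken singly, Trac reached at least 105.03 CPM and Cd3d at least 44.96 CPM in each library. Cd3e and Cd3g also stayed above that floor but came nearer to it, down to 11.06 CPM for Cd3g. The design has no group that separates these cells, so no biological explanation was tested against a group.

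Within the T cell list Foxp3, at 0.62 ± 0.27, and Ctla4, at 0.60 ± 0.23, lay above 0 and Cd8a, at -0.65 ± 0.34, below. With 1 library left out Cd8a ran from -0.92 to -0.40. These genes were chosen after their values were seen, and none passed over all genes. A score of 10 regulatory T cell genes, 5 of them also in the fixed lists, was higher in DRQ by 0.54 (exact 2-sided permutation p = 0.0286), and a score of 2 CD8 genes differed by -0.27 (DRQ minus PBS, exact 2-sided permutation p = 0.371). The difference between the scores, 0.81 (exact 2-sided permutation p = 0.0857), did not pass. A larger share of all T cell RNA cannot be told apart from a change in T cell types, because the CD8 score rests on 2 genes.

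All 35 splits of the 8 libraries into 4 and 4 were refitted. As many genes as the real 2 were called in 2 of the 35 splits, the real one included, so chance was not excluded for the gene count. The other of these splits called 9 genes and exchanged PBS replicate 3 and DRQ replicate 1. Of the 35 the real split had the most genes at an unadjusted p under 0.05 by edgeR (447, highest other 416), a measure looked at after the count. Whether the samples hold a structure other than the treatment was not tested. At the preset correlation, as many function lists as the real 10 were called in 1 of the 35 splits, the real one. The highest other had 9. That share lay under the bound of 0.05 set beforehand, but it is the smallest that 35 splits can give. The real split gave 0 calls with an estimated correlation and 6 without PBS replicate 2. Permutation with adjustment gave 0, though it could hardly have called any list. Chance was thus not taken as excluded for these lists. As many cell type lists as the real 3 were called in 4 of the 35, with 5 in the highest other, so chance was not excluded there.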
